A study of Rattus norvegicus with 6 samples.

How the data were processed

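The data are gene counts of 6 RNA-seq libraries from cultured rat cells, 3 treated with a control siRNA and 3 with an siRNA against Mt2; groups and replicate numbers were read from the sample titles. Per the labels' protocols, total RNA was taken with a silica column kit and libraries were made with a SMARTer mRNA-seq kit. The same protocol text, shared by all 6 samples, also names dexamethasone, isobutylmethylxanthine and insulin in a feeding schedule of the kind used to make fat cells; whether these cells received it is not given in the sources used here. The submitters' processing notes name Trimmomatic 0.40, HISAT2 2.2.1, featureCounts, limma, DESeq2 and the rat genome build rn6, without saying in which order or with which settings they were used. The authors deposited 1 file of raw whole-number counts per gene and library, and no normalization had been applied to these counts. How featureCounts treated reads that match several genes, and whether it used strand, is not given in the sources used here; levels of genes with near-identical copies or overlapping neighbours are therefore uncertain.

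All 6 files hold the same 18237 rows in the same order, and each row has a summed count of at least 2. There were 25 rows whose gene names had been turned into dates by a spreadsheet, with 2 of these names occurring again; they carry 0.260% of the counts and stayed in library sizes and tests but are not named. No row was a total or an unassigned class, and 0 columns were left without a sample. Of the row names, 14407 match a symbol and 744 a synonym in a table of RefSeq genes of assembly GRCr8, which was used for names only; no coordinates are given because it is not the build of the counts. Some heart genes, such as the beta myosin heavy chain, were not analysed here.

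Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM, and the groups were compared by the quasi-likelihood test with robust dispersion estimates, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values and SD are TMM-scaled unless a value is called a share of the library total. Log2 fold changes are libraries labelled siMt2 over siNT. Mt2a and Mt1 were also compared by an exact two-sided permutation test over 20 assignments. The common biological coefficient of variation was 0.0665 and the median log2 fold change of all genes was 4.90e-04. The depth of 2859759 to 6817777 counts per library sets the precision: 3 counts, the limit that a count of 0 allows, equal 0.440 to 1.05 CPM. Intervals of pooled counts are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only, since reads carry no molecular identifiers.

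The 31 gene lists were written before the data were examined, as were the test, the alternatives and the rule for naming genes. That rule names all measured metallothioneins; the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05, mean CPM of at least 5 and groups that do not overlap, leaving out names that give only a locus or clone; and up to 4 members of each list with the smallest adjusted p. Text says where a gene was named after its values were seen. The result of 1 list is not reported here. Lists with at least 3 tested genes (27) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. Camera called 11 lists (9 up, 2 down), the estimated correlation kept 2 of the calls, the cell cycle and NRF2 lists, and fry called 20.

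The procedure was tested on simulated counts drawn for the same 11726 genes from the means and depths of these libraries, with 200 genes changed and, besides them, 1 list shifted. For this comparison it recovered 70% of genes changed by 0.5 on the log2 scale, 79.5% of those changed by 1 and 95.5% of those changed by 2, with 8.67% of the calls false; 0 of 30 unshifted lists and the shifted list were called. Pairs of libraries were compared by chi-square over genes: pairs within a group differed by 1.58 to 2.29 times the counting expectation at the median, so none was taken as a repeat of another, and pairs across groups by 8.54 to 12.2 times.

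Alternatives tried were DESeq2's size factors and upper quartile scaling in edgeR, no filter, a stricter filter (at least 10 counts in every library of a group and mean CPM of at least 1), the replicate number as a block, each library left out in turn, DESeq2 1.42.0 and limma-voom (limma 3.58.1). Chosen after seeing the data were libraries thinned to the depth of the smallest one, and the removal of rows whose replicates scatter by a coefficient of variation over 0.3 beyond counting error.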

Results

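RNA sequencing was performed on total RNA of cultured rat cells described as NRVM, the usual abbreviation for neonatal rat ventricular myocytes, although the growth protocol speaks of embryonic myocardium. The cells had received a control siRNA (siNT, n = 3 libraries) or an siRNA against Mt2 (siMt2, n = 3 libraries). Mt2 encodes a metallothionein, a small cysteine-rich protein that binds zinc and copper. The comparison asks which transcripts differ once Mt2 is targeted, within a project on the translation initiation factor subunit eIF3m and nitrative damage after ischemia and reperfusion. Gene counts summed to 5561522, 4216586 and 6567793 in the siNT libraries and to 6817777, 4220831 and 2859759 in the siMt2 libraries, so a count of 3 corresponded to between 0.440 and 1.05 CPM, the count scaled to a common library total. Nothing in the labels says that the replicates of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

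The targeted transcript was not measurably lower in the libraries labelled siMt2. Mt2a, the rat Mt2 gene, stood at 90.7, 170 and 93.3 CPM in the siNT libraries and at 70.7, 87.3 and 142 CPM in those labelled siMt2. The means were 118 ± 45.0 and 99.9 ± 37.3 CPM (SD, n = 3 each), a log2 fold change of -0.28 (SE 0.42, 95% interval -1.42 to 0.87), with an edgeR adjusted p of 0.631. The exact two-sided permutation test gave p = 0.5, where 0.1 is the smallest p that 3 against 3 libraries allow. The interval reaches from 0.372 to 1.82 times the siNT level. With 1 library left out in turn, the log2 fold change lay between -0.56 and 0.052 (edgeR adjusted p = 0.358 and 0.923). The first was without siMt2 replicate 3, the highest of its group, and the second without siNT replicate 2, the highest of all. Over the alternatives the adjusted p lay between 0.264 (limma-voom) and 0.954 (edgeR without siMt2 replicate 1). The replicates of Mt2a varied by 38.1% (siNT) and 37.3% (siMt2) of their mean, whereas the counting error of its smallest count, 369, was 5.21%. The other metallothionein measured, Mt1, was close to the detection limit at 2.48 ± 0.142 and 4.0 ± 0.761 CPM (log2 fold change 0.72, SE 0.34, 95% interval 0.0094 to 1.44, edgeR adjusted p = 0.0819). All 3 Mt1 values labelled siMt2 lay above the siNT values, and the exact permutation p was 0.1, the smallest possible here. Because the knockdown was not visible in the transcript, groups are named below by their labels.

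**Figure D1:**
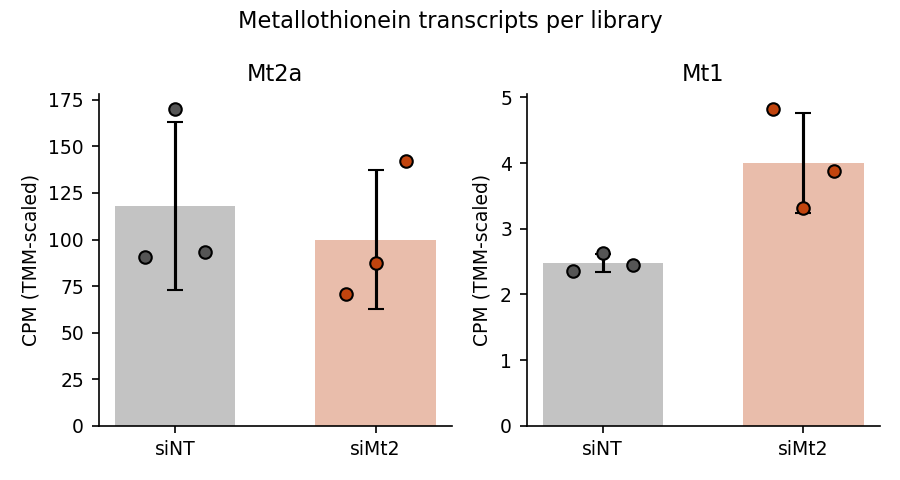
Levels of Mt2a and Mt1 in CPM after TMM scaling, by library group on the x axis. Points are single libraries, bars are means and error bars are SD (n = 3); the Mt2a values of both groups overlap, at 118 ± 45.0 and 99.9 ± 37.3 CPM.

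The libraries labelled siMt2 nevertheless differed from the siNT libraries over much of the transcriptome. Mitotic, inflammatory and hypoxia-inducible genes were among those with the largest rises, and a chaperone, a mitochondrial carrier and an interferon-inducible gene were among the largest falls. Of 11726 genes tested, 5971 (50.9%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3026 higher and 2945 lower in the libraries labelled siMt2. Changes beyond 1 on the log2 scale were less even, with 746 genes higher and 305 lower. All 3 libraries of a group lay on one side of all 3 of the other for 6756 genes (57.6%), where chance gives 10% for 3 against 3. The first principal component, with 66.9% of the variance, separated the groups, and the second, with 12.4%, set siMt2 replicate 3 (-26.4) apart from siMt2 replicates 1 and 2 (9.57 and 18.8). Without siMt2 replicate 3, which also had the lowest total, 6254 genes passed. Pearson correlations of log2 CPM across genes, which are not independent replicates, lay between 0.979 and 0.988 within groups and between 0.944 and 0.953 across groups.

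The largest rise among genes meeting the naming rule was that of Col6a3, a collagen VI chain, from 0.473 ± 0.690 to 14.0 ± 4.05 CPM (log2 fold change 4.77, SE 0.51), although its siNT counts were 7, 0 and 1 and its replicates scattered beyond counting error. Its fitted log2 fold change was 6.89 without siNT replicate 1, which leaves siNT counts of 0 and 1, and 6.53 with libraries thinned to equal depth, an alternative chosen after seeing the data. Adm, which encodes the vasodilator peptide adrenomedullin, rose from 8.74 ± 3.43 to 123 ± 8.31 CPM (3.80, SE 0.16). Cxcl1, a neutrophil-attracting chemokine, rose from 10.9 ± 2.21 to 123 ± 4.94 CPM (3.45, SE 0.11). The cytokine subunit gene Il23a (3.24, SE 0.30), the adhesion molecule gene Vcam1 (3.24, SE 0.29), Nabp1 (3.15, SE 0.18), Oip5 (3.06, SE 0.39), the mitotic cyclin gene Ccnb1 (3.02, SE 0.14), the AMP deaminase gene Ampd3 (3.01, SE 0.25) and the spindle protein gene Nusap1 (3.00, SE 0.19) followed. The replicates of Oip5, whose siNT counts were 12, 3 and 4, also scattered, and without siNT replicate 1 its log2 fold change was 3.88. The edgeR adjusted p of these 10 genes was at most 1.50e-06.

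The deepest fall among genes meeting the naming rule was that of Trem3, a receptor of the family found on myeloid cells, from 16.6 ± 1.29 to 0.939 ± 0.232 CPM (log2 fold change -4.01, SE 0.29). Slc25a48, a mitochondrial carrier gene, fell from 67.0 ± 1.07 to 9.67 ± 1.73 CPM (-2.74, SE 0.13) and Ypel1 from 77.4 ± 4.45 to 12.1 ± 0.149 CPM (-2.67, SE 0.11). Hspa4l, a member of the Hsp110 chaperone family, was the most abundant of these genes and fell from 301 ± 13.5 to 68.3 ± 3.71 CPM (-2.15, SE 0.06). The sodium-proton exchanger gene Slc9a3 (-2.45, SE 0.34), Mamdc4 (-2.21, SE 0.25), Prdm10 (-2.02, SE 0.21), Nagpa (-2.01, SE 0.30), the interferon-inducible Ifi44 (-1.98, SE 0.22) and the pseudokinase gene Trib2 (-1.97, SE 0.14) fell as well. The edgeR adjusted p of these 10 genes was at most 1.21e-05.

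**Figure D2:**
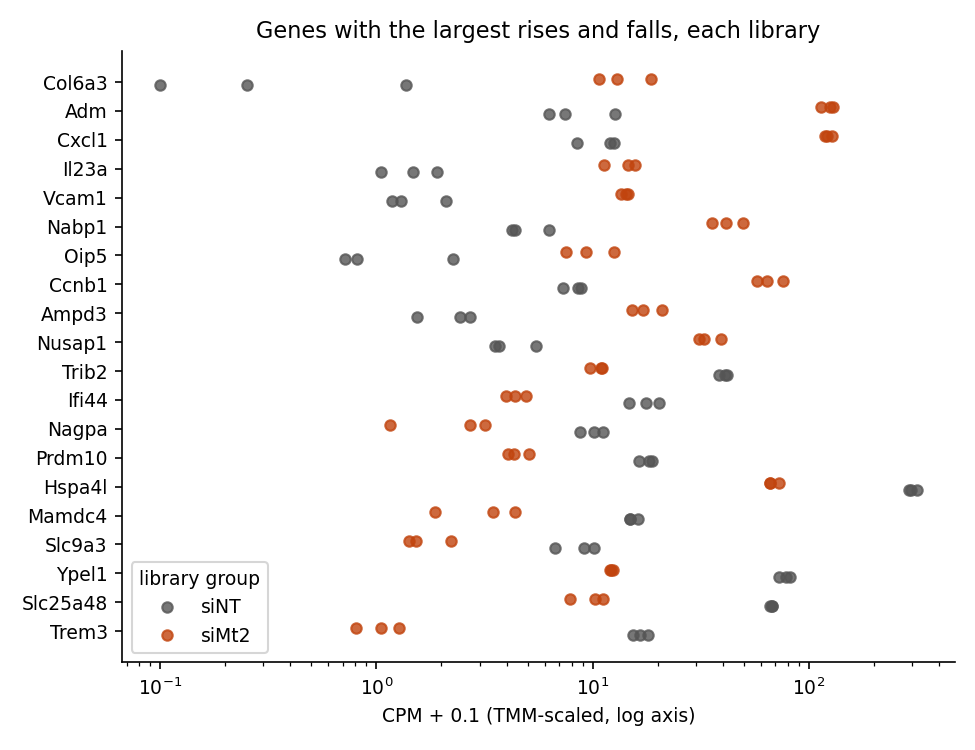
CPM plus 0.1 after TMM scaling (x axis, logarithmic) of the 10 genes with the largest rises and the 10 with the largest falls (y axis). Each point is a library; for each gene all 3 siMt2 points lie on one side of all 3 siNT points, as the naming rule requires.

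Gene groups fixed in advance were compared next, and most cell cycle genes were higher. Of 48 cell cycle genes tested, 36 rose and 4 fell in the libraries labelled siMt2 (37 and 4 adjusted over the list alone). Top2a, the topoisomerase that untangles replicated chromosomes, rose from 46.2 ± 1.93 to 200 ± 11.3 CPM (log2 fold change 2.10, SE 0.07). The proliferation marker Mki67 (1.68, SE 0.06) and the G1 cyclin gene Ccnd1 (1.20, SE 0.04) rose with it, besides Ccnb1. The list was called by camera (adjusted p = 4.76e-26) and also with an estimated correlation between its genes (adjusted p = 0.00515).

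NRF2 targets and antioxidant genes rose in part: 18 of 28 were higher and 8 lower, with the same counts adjusted over the list alone. Gstp1, a glutathione transferase, rose from 442 ± 13.9 to 1066 ± 22.6 CPM (log2 fold change 1.27, SE 0.04). The heme oxygenase gene Hmox1 doubled in level, from 515 ± 18.5 to 1078 ± 32.6 CPM (1.07, SE 0.04), and Nqo1 (1.00, SE 0.05) and the thioredoxin reductase gene Txnrd1 (0.88, SE 0.04) rose. Members that fell included the superoxide dismutase gene Sod1 (-0.50, SE 0.08) and the glutathione peroxidase gene Gpx1 (-0.64, SE 0.08), both named after their values were seen. Camera called the list upward (adjusted p = 1.79e-09), and so did the test with an estimated correlation (adjusted p = 0.0270).

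Glycolytic and hypoxia-inducible genes were higher in 20 of 25 cases and lower in 1, Pkm, named after its value was seen (log2 fold change -0.64, SE 0.08); 21 and 1 passed adjusted over the list alone. Besides Adm, the carbonic anhydrase gene Car9 rose from 11.6 ± 0.386 to 79.3 ± 6.91 CPM (2.75, SE 0.12), the mitophagy receptor gene Bnip3 from 128 ± 6.53 to 300.3 ± 1.36 CPM (1.24, SE 0.05) and the lactate dehydrogenase gene Ldha from 513 ± 12.4 to 924 ± 23.8 CPM (0.85, SE 0.04). Of 18 NF-kB and inflammatory cytokine genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone), among them, besides Cxcl1 and Vcam1, the NF-kB inhibitor gene Tnfaip3 (1.45, SE 0.12) and the monocyte chemokine gene Ccl2 (1.56, SE 0.14). Camera called both lists upward (adjusted p = 7.05e-10 and 1.05e-07), but neither passed with an estimated correlation (adjusted p = 0.0689 for each).

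Extracellular matrix and TGF-beta genes went both ways, with 14 of 30 higher and 8 lower. Sparc, a matrix protein gene, rose from 752 ± 8.42 to 1791 ± 58.9 CPM (log2 fold change 1.25, SE 0.04), and Tgfbi (2.73, SE 0.11), the periostin gene Postn (1.25, SE 0.06) and the collagen VIII gene Col8a1 (1.53, SE 0.09) rose. Contractile genes rose too: 8 of 11 smooth muscle and pericyte markers were higher and 1 lower, with Tagln going from 331 ± 8.71 to 1103 ± 41.8 CPM (1.74, SE 0.04), the smooth muscle actin gene Acta2 from 1502 ± 32.2 to 2626 ± 39.3 CPM (0.81, SE 0.03) and the receptor gene Pdgfrb falling (-0.46, SE 0.05). Of 19 sarcomere genes in the counts only 8 passed the filter for testing, of which 6 rose and 1 fell. Tpm1 (0.62, SE 0.04), Tnnc1 (1.58, SE 0.11), Tnnt2 (1.01, SE 0.11) and the desmin gene Des (1.84, SE 0.23) had the smallest adjusted p among them. Fibroblast markers were higher in 7 of 10 cases and lower in 0, with Vim at 1057 ± 28.9 and 1692 ± 53.8 CPM (0.68, SE 0.04) and Thy1 at 264 ± 16.1 and 461 ± 29.5 CPM (0.80, SE 0.05). These 4 lists had the same counts adjusted over the list alone. Camera called all 4 upward (adjusted p = 3.89e-06, 1.95e-05, 0.00176 and 0.00176 in the order given), and each missed the threshold with an estimated correlation (adjusted p = 0.0689).

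Chaperone genes that changed were mostly lower, and most autophagy and lysosome genes did not pass. Of 18 heat shock and chaperone genes, 10 were lower and 3 higher: Hspa8, the constitutive Hsp70, fell from 1653 ± 30.9 to 641 ± 4.18 CPM (log2 fold change -1.37, SE 0.04), Hsph1 from 759 ± 3.71 to 337 ± 20.3 CPM (-1.18, SE 0.05), and Dnaja1 (-0.85, SE 0.05) and Cryab (-0.78, SE 0.07) fell as well. Of 28 autophagy and lysosome genes, 9 fell, 4 rose and 15 did not pass; the lysosomal membrane protein gene Lamp1 (-0.83, SE 0.04), the autophagosome marker gene Map1lc3b (-0.75, SE 0.05) and the cathepsin genes Ctsb (-0.44, SE 0.04) and Ctsd (-0.39, SE 0.03) were among those that fell. Both were called downward by camera (adjusted p = 1.09e-05 and 0.0312) and not with an estimated correlation (adjusted p = 0.0689 and 0.131). Under upper quartile scaling the autophagy list also missed camera's threshold (adjusted p = 0.0512). Counts adjusted over the list alone were the same for both.

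Mitochondrially encoded transcripts were slightly higher, 10 of 13 up and 1 down, with the same counts adjusted over the list alone; ATP6 (log2 fold change 0.39, SE 0.04), ND2 (0.50, SE 0.05), ND4L (0.43, SE 0.05) and ND5 (0.39, SE 0.04) were among those that rose. They took between 3.52% and 3.80% of the counts in 5 libraries and 4.18% in siMt2 replicate 3. COX1, the gene with the most counts in every library, went the other way. It took 1.49%, 1.48% and 1.53% of the counts in the siNT libraries and 1.30%, 1.31% and 1.43% in those labelled siMt2. Camera called the list (adjusted p = 0.00434), but with an estimated correlation of 0.555 between its genes it did not pass (adjusted p = 0.648).

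**Figure D3:**
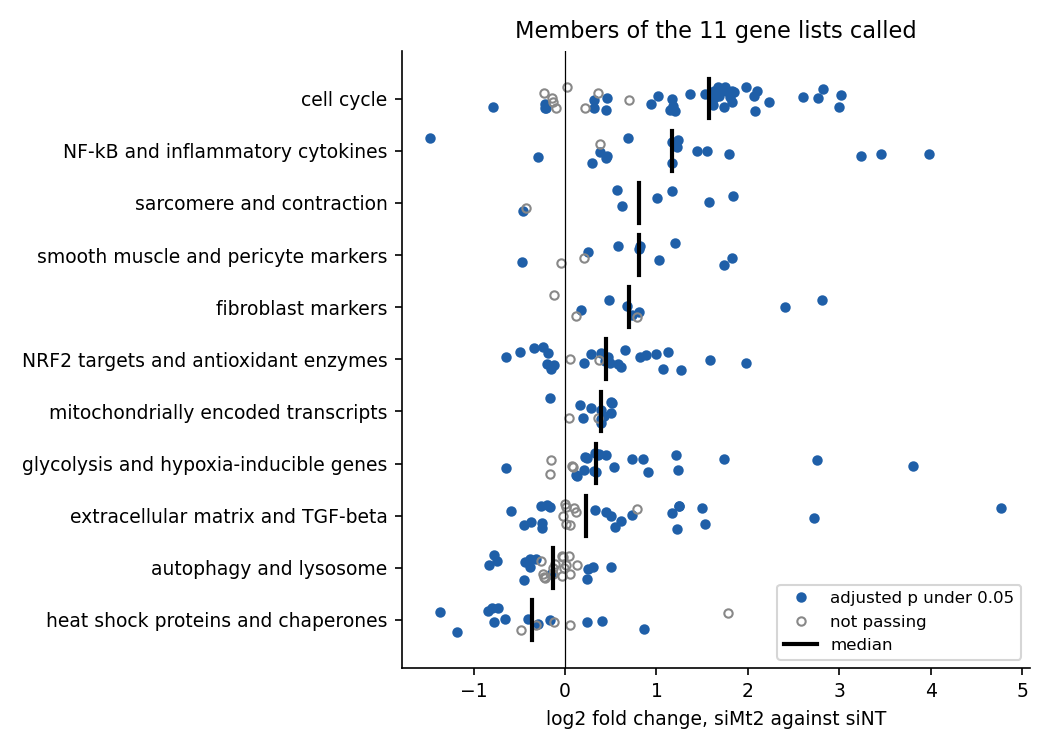
Log2 fold changes, libraries labelled siMt2 against siNT (x axis), of the members of the 11 gene lists called by camera (y axis). Each point is a gene, filled where its edgeR adjusted p was under 0.05, and black bars mark the medians, from -0.36 for chaperones to 1.57 for the cell cycle.

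The remaining 16 lists tested were not called by camera, though they held genes that changed, as 50.9% of all genes tested did. Zinc and copper handling genes were higher in 3 of 21 cases and lower in 7, including the zinc transporter genes Slc39a6 (log2 fold change -0.87, SE 0.06) and Slc30a4 (-0.49, SE 0.05). Of 25 nitric oxide and superoxide genes in the counts, 13 passed the filter for testing, of which 3 rose and 5 fell. The xanthine dehydrogenase gene Xdh fell from 179 ± 2.00 to 60.9 ± 3.28 CPM (-1.57, SE 0.07) and the caveolin gene Cav1 rose (0.70, SE 0.05). The nitric oxide synthase genes Nos2 and Nos3 were close to absent, with 5 and 3 counts over all 6 libraries. The subunits of eIF3 went both ways, 3 of 13 higher and 7 lower: Eif3m, the subunit the project is about, rose from 142 ± 0.551 to 193 ± 17.7 CPM (0.44, SE 0.06) and Eif3e rose (0.47, SE 0.06), while Eif3c (-0.94, SE 0.04) and Eif3f (-0.50, SE 0.06) fell. Camera's adjusted p was 0.256, 0.280 and 0.305 for these 3 lists. Fry, which does not compare a list with other genes, called all 3 downward (adjusted p = 0.0141, 0.0233 and 0.0233).

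Calcium handling genes rose in 4 of 11 cases and fell in 3, with the calsequestrin gene Casq2 higher (log2 fold change 1.16, SE 0.06) and the calcium pump gene Atp2a2 lower (-0.50, SE 0.04). Fetal and hypertrophy genes rose in 5 of 15 and fell in 6, with Ankrd1 higher (0.83, SE 0.05) and Fhl1 (-0.91, SE 0.04) and Mef2c (-1.38, SE 0.07) lower. Of 72 nuclear-encoded oxidative phosphorylation genes 13 rose and 17 fell, and of 24 fatty acid oxidation genes 10 rose and 6 fell. The unfolded protein and integrated stress response list had 13 of 31 higher and 6 lower: Ddit3 (1.63, SE 0.08) and Ppp1r15a (1.12, SE 0.06) rose, while the endoplasmic reticulum chaperone genes Hsp90b1 (-0.59, SE 0.04) and Hyou1 (-0.79, SE 0.05) fell. Of 26 p53 target and apoptosis genes 6 rose, Fas among them (1.53, SE 0.08), and 9 fell, Mdm2 (-0.83, SE 0.04) and Cdkn1a (-0.71, SE 0.05) among them. The interferon list had 11 of 29 higher and 8 lower, the glucocorticoid list 5 of 14 higher and 4 lower, and the cytosolic ribosomal proteins 27 of 75 higher and 22 lower. The extract protocol of both groups names the glucocorticoid dexamethasone, isobutylmethylxanthine and insulin, without saying that these cells received them. Whether these compounds bore on the levels of glucocorticoid, adipocyte and metabolic genes was not tested. Cholesterol and fatty acid synthesis genes were higher in 12 of 29 cases and lower in 7. Median, mean and camera's direction did not share a sign for the calcium, unfolded protein, p53, interferon and glucocorticoid lists. Counts adjusted over the list alone were 14 higher and 7 lower for cholesterol synthesis and 5 and 5 for glucocorticoid genes, and otherwise as given for the lists of these paragraphs.

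Apart from the fibroblast and smooth muscle lists described above, markers of other cell types were few. Endothelial markers (0 of 4 higher, 1 lower, Eng), adipocyte markers (0 of 3 higher, 1 lower, and 0 lower adjusted over the list alone) and epicardial markers (2 of 4 higher, 1 lower) were not called by camera. The adipocyte gene that passed, Lipe, lay at 2.80 ± 0.686 and 1.28 ± 0.735 CPM, and its call was lost without siNT replicate 2 (edgeR adjusted p = 0.141), siNT replicate 3 (0.0644) or siMt2 replicate 1 (0.294, log2 fold change -0.68 in place of -1.28). Lists with fewer than 3 genes tested received no camera test; among them were metallothioneins (2 genes, 0 passing), leukocyte markers (Cd14, which fell, log2 fold change -0.73, SE 0.15) and Schwann cell and neuronal markers (Dbh and Tubb3, both higher, 2.37 and 1.54).

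Several transcripts typical of heart muscle were close to absent from both groups. Over all 6 libraries together, the alpha myosin heavy chain gene Myh6 had 9 counts, the cardiac actin gene Actc1 4, the cardiac troponin I gene Tnni3 3, Mybpc3 4, Myl7 6, the natriuretic peptide gene Nppb 2, the ryanodine receptor gene Ryr2 24 and the phospholamban gene Pln 51, of 30244268 in all. The exact 95% upper limit of the pooled level, which covers counting error only, was 0.565 CPM for Myh6 and 2.22 CPM for Pln. Tnnt2 and Tnnc1 were measurable, at 27.2 ± 1.38 and 25.5 ± 2.02 CPM in the siNT libraries. These levels and those of other muscle genes were compiled after the counts were seen.

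**Figure D4:**
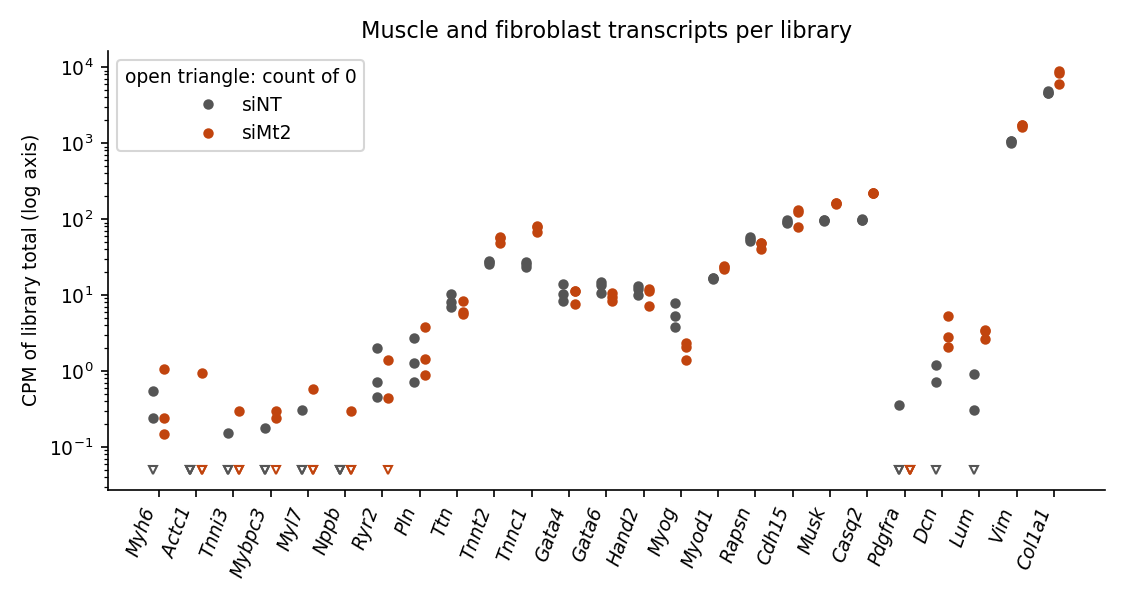
CPM of the library total (y axis, logarithmic) of muscle, cardiac regulator and fibroblast transcripts (x axis) in each library; open triangles mark a count of 0. Myh6 to Nppb stayed at or below 1.05 CPM in all 6 libraries, while Myod1 stayed at or above 16.4 CPM.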

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

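Thinning to equal depth and leaving out rows with scattering replicates were chosen after seeing the data. The number of genes changed lay between 4961 (DESeq2) and 6276 (no filter) over 15 alternatives, against 5971, and from 5109 to 6254 with 1 library left out; the genes shared with those 5971 had the same direction in each alternative (4941 shared in DESeq2). Genes higher numbered 2601 to 3162 and genes lower 2481 to 3092 with 1 library left out, and genes beyond 1 on the log2 scale 1044 to 1138. Upper quartile scaling moved the share of higher genes from 50.7% to 55.4%. The Mt2a fold change stayed short of the threshold in the 14 alternatives that gave a value (adjusted p 0.264 to 0.954), at -0.56 to 0.052 on the log2 scale with 1 library left out; it turned positive, at 0.052, only without siNT replicate 2, and its row, like those of Col6a3, Oip5, Lum, Dcn and Tubb3, is itself one with scattering replicates, so these have no value without them. Mt1, Lum, Lipe and Dcn gave no value after thinning, nor Lipe without siNT replicate 1. Over the alternatives Col6a3 lay between 4.25 and 6.89, Oip5 between 2.69 and 3.88, Lum between 2.38 and 3.91 and Dcn between 1.71 and 3.13. Camera called 10 lists with upper quartile scaling and 11 in every other alternative that kept camera at its preset correlation. Fry, which does not compare a list with other genes, called 20. The estimated correlation called 2. For the sarcomere, fibroblast and autophagy lists, which lost their calls, it was -0.091, -0.035 and -0.024, below the preset 0.01. Stronger correlation between genes therefore does not account for the loss of these calls. The other lists that lost their calls had estimates above 0.01, but stronger correlation need not be the cause there either. Under this setting p also rose for lists that kept their calls with estimates below 0.01. Camera's adjusted p went from 4.76e-26 to 0.00515 for the cell cycle list (estimate -0.0045). For the NRF2 list (estimate -0.022) it went from 1.79e-09 to 0.0270. What part correlation had in the other losses was not tested. Replicate numbers did not pair the samples (same-number correlations of deviations -0.020, -0.073 and 0.046, and 1 of 3 siNT libraries closest to its own number); with the replicate block 5897 genes changed (2968 higher, 2929 lower, 1060 beyond 1), the Mt2a fold change was -0.25 and 11 lists were called. Of the 137 genes named by the rule or after their values were seen, Lipe (no filter, DESeq2 and 3 of the left-out libraries) and Pcna (upper quartile scaling, DESeq2, thinning and 3 of the left-out libraries) lost their calls and Mt1 gained one, without scattering rows (adjusted p = 0.0364, against 0.0364 to 0.333 over its alternatives); 0 of these genes and 0 lists that were called reversed. With every library thinned to the smallest total 5115 genes changed, 4953 of them shared with the 5971.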

Other observations

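The cell cycle list did not move as one block. After the values were seen, some of its 48 tested genes were divided into a mitotic and a DNA replication part, and the rest were left out. Of 26 mitotic genes 25 rose and 0 fell (median log2 fold change 1.75), among them Cdc20 (2.82, SE 0.20) and Aurka (2.23, SE 0.25). Of 14 DNA replication genes 6 rose and 4 fell (median 0.17), with Tk1 higher (1.74, SE 0.17) and Tyms lower (-0.78, SE 0.18). Pcna was lower as well (-0.22, SE 0.08), but its call was lost without siNT replicate 1 (edgeR adjusted p = 0.0771), siNT replicate 2 (0.0990) or siMt2 replicate 1 (0.145), with upper quartile scaling (0.0642), in DESeq2 (0.0845) and after thinning to equal depth, chosen after seeing the data (0.190), within a range of 0.0179 to 0.190 over its alternatives. The difference between the parts was not tested, since they were divided on these values.

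The gene with the smallest p-value of all was H19, an imprinted noncoding RNA, which rose from 347 ± 4.73 to 1827 ± 122 CPM (log2 fold change 2.40, SE 0.05), and its imprinted neighbour Igf2, the growth factor gene, rose from 43.7 ± 2.99 to 158 ± 5.05 CPM (1.85, SE 0.07). A list of 12 imprinted genes, written after H19 had been seen, had 3 higher, Peg3 the other (0.55, SE 0.06), and 6 lower, such as Peg10 (-1.17, SE 0.35) and Gnas (-0.41, SE 0.05). Its camera direction (adjusted p = 0.0243, and 0.115 with an estimated correlation) is opposite in sign to its median of -0.15.

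In the weighing that follows, the tests on splits and depth were stated before their results were seen, and the others after. Mt2a was not measurably lower in the libraries labelled siMt2. A swap of part of the libraries between the groups is argued against, since 0 of the 6 libraries had their closest library in the other group, but an exchange of all labels would give the same count and stays open, as the interval of the Mt2a log2 fold change of -0.28 includes 0 (-1.42 to 0.87). Reads moved between Mt2a and near-identical copies are a candidate explanation that stays open. The scatter of Mt2a replicates was at percentile 99.8 of 3386 genes of like level. The explanation also predicted that rows with scattering replicates would be richer in genes with a named pseudogene. Among the 10393 genes with a mean CPM of at least 5, leaving out names that give only a locus, they were not measurably richer (odds ratio 0.935, 95% interval 0.503 to 1.62, Fisher's exact p = 0.892). The RefSeq symbols name no pseudogene of Mt2a itself, so this comparison over other genes cannot decide the question for Mt2a. As first written, the prediction took any odds ratio without enrichment as counting against the explanation. After the value was seen, the rule was changed to ask that the whole interval show no enrichment. Names that give only a locus were more frequent among the 164 of these 10393 genes whose replicates scattered (odds ratio 6.23, Fisher's exact p = 5.89e-20), a comparison made after the pseudogene test had been seen. A knockdown lost by the time of harvest, or one that acts on the protein, was not tested.

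The breadth of the difference between the groups has several possible sources. None of the other 9 splits of the 6 libraries into 3 and 3 gave as many genes as the real one. It was 1 of 10, with 5971 genes against a highest other of 0, but 10 splits are too few for a share under 0.05. Each other split also put libraries of both groups on each side, where the group difference adds to the spread within a side. The 0 genes of those splits are therefore no measure of what chance gives. Unequal depth is argued against as the whole cause, with 5115 genes changed after thinning. Replicates that are repeats of 1 culture per group cannot be told apart from separate cultures: the largest within-group median difference was 2.29 times the counting expectation, which both allow. A difference between the 2 groups of cultures other than the siRNA, such as density or time of harvest, and an effect of this siRNA beyond Mt2, are confounded with the labels.

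Several heart muscle transcripts were close to 0 in cells described as ventricular myocytes, while Tnnt2 and Tnnc1, at 27.2 and 25.5 CPM in the siNT libraries, and Casq2 were measurable. Too few reads do not account for this, as the highest upper limit over 8 such genes was 2.22 CPM. Heart fibroblasts in place of muscle cells stay open. The upper limit for the level pooled over the 6 libraries was at most 2.22 CPM for Pdgfra, Dcn and Lum. These genes were chosen with their values already seen, so they cannot decide it. Col1a1, Vim and Thy1 were abundant, as was Ddr2 of the fibroblast list, at 630 and 882 CPM in the siNT and siMt2 libraries. Dcn and Lum rose in the libraries labelled siMt2, to at most 5.25 and 3.50 CPM in a library. A candidate explanation is a culture of skeletal myoblast type, as in lines grown from embryonic rat heart. Myod1, Cdh15, Musk and Rapsn, chosen after the counts were seen, did not go below 16.4 CPM in any library. Of 16 genes on a skeletal myogenic list written after these counts were seen, 8 rose and 3 fell in the libraries labelled siMt2 (camera adjusted p = 0.615), with Myog lower (log2 fold change -1.47, SE 0.37) and Tnnc2 higher (0.94, SE 0.14). Some members of this list were low in both groups. Their siNT and siMt2 means were 5.62 and 1.94 CPM for Myog, 2.46 and 1.36 for Mylpf, 0.815 and 3.09 for Tmem8c, and 1.82 and 3.92 for Ryr1. The regulators Gata4, Gata6 and Hand2, which heart cells also use, were measured at 10.3, 11.2 and 10.4 CPM pooled. Nkx2-5, another such regulator, was low, at 1.72 CPM pooled, which does not speak against a skeletal type. Since the skeletal genes were chosen after the counts were seen, a skeletal myoblast type stays a hypothesis.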
